A study of Mus musculus with 6 samples.

How the data were processed

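RNA was measured in 6 mouse tumors grown from 4T1, a mouse line used as a model of triple-negative breast cancer. The labels place 3 tumors before the first peak of neural activity and 3 on the day of that peak. Per the labels' protocols, RNA was extracted with Trizol from snap-frozen tissue, selected with oligo(dT) and sequenced as paired-end libraries without strand marking. The deposited values are raw counts per gene, whole numbers with no normalization, and each tumor has its own column. Per the submitters' processing notes, FastQC, STAR and the mm10 build were used, with no versions. The read counter, the gene annotation behind the counts and any filter on genes are not given in the sources used here. Without strand, reads from overlapping genes on opposite strands cannot be told apart. Of the genes named in the text, Adrb3, Alas2, Chrnb2, Ftl1, Il1b, Krt5, P2rx3, Pxdc1 and Ryr1 overlap a tested gene on the opposite strand, and Cx3cr1 and Spp1 overlap other tested genes, so their counts are uncertain to that extent. The same holds for Chil3, Hbb-bt, Mcpt1 and Mcpt2, which have close paralogs.

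The table held 23508 genes under Ensembl identifiers, of which 5 had no count in any library and 23479 matched the GENCODE M21 annotation of GRCm38, the assembly that mm10 also names. Symbols and coordinates were taken from that annotation. Total counts ran from 10591067 to 14549357 per library, so a gene near 1 CPM (counts scaled to library size) rests on few counts and carries large counting error. Pairs of libraries of the same group differed by a chi-square of 17.1 to 28.9 per degree of freedom over genes, far above sampling noise, so that no library was counted as a duplicate of another. The labels do not say whether the tumors came from separate animals, so the p-values measure only the spread between these samples.

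Counts were analysed with edgeR 4.0.16 and limma 3.58.1 in R 4.3.3. Library sizes were scaled by TMM. Genes were kept by filterByExpr with a minimum count of 10 and a minimum total count of 15, which left 16755 genes. The main test was the edgeR quasi-likelihood test (robust, two-sided) of with-peak against before-peak tumors with no covariate, with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes are log2 of with-peak over before-peak tumors. The standard error (SE) of a log2 fold change was computed as its size divided by the square root of the F statistic. CPM values are TMM-normalised and given as mean ± SD over 3 tumors.

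Gene lists for nerve, cell state, cell type and RNA quality were fixed before the data were examined, as were the tests, the rule for named genes and most of the alternatives. The 34 lists held 735 memberships, of which 582 were tested. Members that were not tested fell below the filter or were not analysed here. The 32 lists with at least 5 tested members were compared with the other genes by camera in limma, with a preset correlation of 0.01 between members and Benjamini-Hochberg adjustment over lists. Camera was repeated with the correlation estimated per list, and fry was run as a test of whether a list's genes move one way. Within each list, p-values were also adjusted over the list alone, with no correction over lists. Of the 582 tested memberships, 36 passed in that way. A list score is the mean log2 CPM of its tested members with a prior count of 2. Scores were compared by a two-sided exact permutation test, whose smallest possible p with 3 against 3 tumors is 0.1.

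The rule for named genes took the strongest genes past the threshold and, where none passed, the 10 with the smallest p-values, given as not passing. It also took up to 2 members with the smallest p-values from each list in which none passed, and a short set fixed by name that includes Th, Dbh, Slc6a2, Npy and Tubb3. Some genes that the rule takes are not reported here. Other genes named in the text were chosen after their values were seen, apart from whole lists fixed in advance. On counts simulated from these libraries for 16755 genes, the edgeR test recovered 35 of 100 genes changed by a log2 of 1 and 84 of 100 changed by a log2 of 2, and called 18 unchanged genes. These are 13.1% of the 137 genes called, above the nominal share of 0.05, so genes that pass the edgeR test may include more false calls than the threshold states. Camera on simulated counts gave p under 0.05 for 3 of 200 unchanged lists. The simulated genes varied independently, while called lists here had estimated correlations such as 0.33 (macrophage) and 0.85 (skeletal muscle). The simulation therefore cannot show how often camera with the preset correlation makes false calls on such lists.

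The alternatives tried were RLE size factors, library size alone, upper quartile scaling, no filter on low counts, at least 1 CPM in at least 3 libraries, DESeq2 1.42.0, limma-voom with and without sample weights, an adjusted p under 0.1, an absolute log2 fold change of at least 1, the replicate number as a block, and leaving out each library in turn. No sample was left out of the main comparison.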

Results

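Gene expression was measured by RNA sequencing in 6 tumors of the mouse mammary carcinoma line 4T1, 3 collected before the first peak of neural activity recorded in the tumor and 3 on the day of that peak. The comparison asks what differs in the tissue when nerve activity, which the series title traces to the sympathetic nervous system, reaches that peak. Total counts were 12262915, 12677637 and 11640276 in before-peak replicates 1, 2 and 3, and 14549357, 13010443 and 10591067 in with-peak replicates 1, 2 and 3. The labels give no tumor age, so the day of collection and the peak cannot be separated.

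Macrophage and monocyte transcripts were higher in with-peak tumors. Of the 24 genes of this list, 22 had a positive log2 fold change, with a median of 0.70, and the list rose relative to other genes by camera (adjusted p = 4.05e-21; adjusted p = 0.427 with an estimated correlation). The list score was 6.67 ± 0.16 before the peak and 7.34 ± 0.27 with it (SD, n = 3, exact permutation p = 0.1), and the groups did not overlap. Nor did they in the share of mitochondrial rRNA counts, 0.0313% to 0.0456% before the peak and 0.0587% to 0.0655% with it. The scores of the erythroid, ribosomal protein and synaptic vesicle lists did not overlap either. Adjusted over the macrophage list alone, 17 members passed the edgeR test and all were higher with peak. Over all genes tested, 0 members passed, while 17 had an unadjusted p under 0.05 and DESeq2 called 11. Arg1, the arginase of myeloid cells (chromosome 10, 24915221 to 24927484), went from 322 ± 68.9 to 617 ± 32.9 CPM, a log2 fold change of 0.94 (SE 0.15; edgeR adjusted p = 0.0976). Gpnmb and Trem2, genes of lipid-handling macrophages, had log2 fold changes of 2.62 and 1.16. Cx3cr1, Spp1 and Mrc1 did not pass, with log2 fold changes of -0.64, -0.22 and 0.07.

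**Figure D1:**
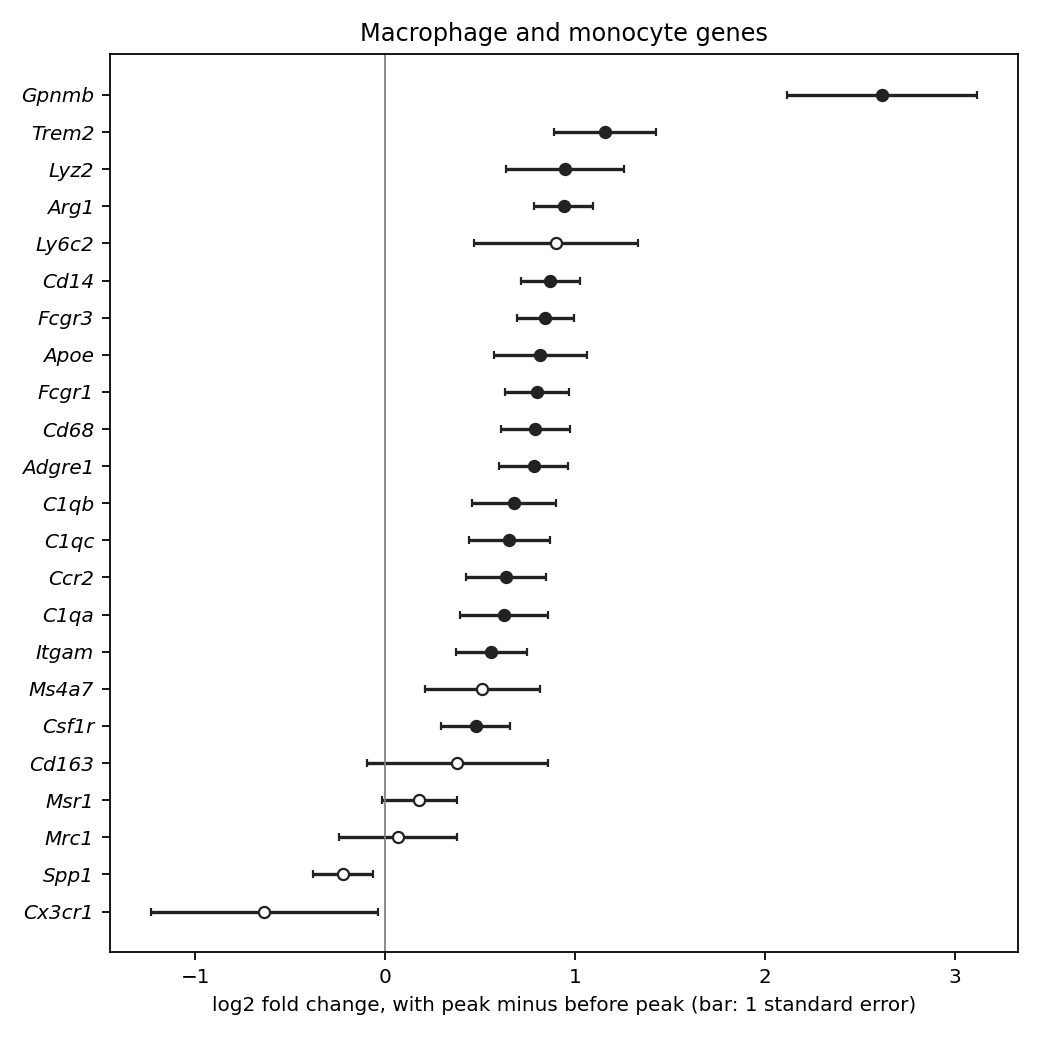
Log2 fold change, with peak minus before peak, of 23 of the 24 macrophage and monocyte genes, with bars of 1 standard error (n = 3 tumors per group). Filled points are the 16 genes drawn that passed the edgeR test adjusted over the list alone; 21 of the 23 points lie above 0.

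The 10 genes with the smallest p-values did not pass over all genes. Of them, 9 were higher in every with-peak tumor than in every before-peak tumor. Choice by smallest p-value favors such separation, so it is no further support. Creg1, a lysosomal glycoprotein (ENSMUSG00000040713, chromosome 1, 165763746 to 165775308), was at 36.1 ± 5.76 CPM before the peak and 82.4 ± 9.07 CPM with it (log2 fold change 1.19, SE 0.15, edgeR adjusted p = 0.0828). Lipa, the lysosomal acid lipase (chromosome 19, 34492318 to 34527474), had a log2 fold change of 0.93 (SE 0.12), and Ftl1, the ferritin light chain, had one of 0.77 (SE 0.10), both with an edgeR adjusted p of 0.0828. Ftl1 overlaps the antisense gene Gm10252. Chil3, a chitinase-like protein of alternatively activated macrophages, was at 1.35 ± 0.28 and 8.42 ± 2.26 CPM (log2 fold change 2.63, SE 0.35). Hal, Hpse, Slc11a1, Apobec1 and Mustn1 had log2 fold changes of 1.57, 1.27, 1.37, 1.18 and 2.40. Pxdc1, which overlaps the antisense gene Gm15908, was the exception, at 57.0 ± 3.57 and 32.3 ± 2.35 CPM (log2 fold change -0.82, SE 0.12, edgeR adjusted p = 0.0976).

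None of the 9 nerve lists with enough tested members passed camera. In the sympathetic list, 8 of 20 genes were tested (adjusted p = 0.937), and its median of -0.21 and mean of 0.16 differ in sign, with camera ranking the list upward. The mixed test of fry, which asks whether genes change in either direction, gave an adjusted p of 0.0419 for the sympathetic, pan-neuronal and macrophage lists and passed no other list. Chga, the chromogranin A of neuroendocrine secretory granules (chromosome 12, 102554969 to 102565028), was at 0.19 ± 0.12 and 2.80 ± 1.26 CPM (log2 fold change 3.83, SE 0.65, edgeR adjusted p = 0.0976) and passed adjusted over the list alone; its before-peak value rests on 7 counts. Slc6a2, the noradrenaline transporter, was at 2.15 ± 2.31 and 0.63 ± 0.24 CPM (edgeR adjusted p = 0.531), with 1 before-peak tumor far above the others. Th, Dbh and Npy were not analysed here, so the result of the list does not cover them. Among pan-neuronal genes (adjusted p = 0.491), Tubb3 was at 1.59 ± 0.38 and 3.34 ± 0.89 CPM and Mapt at 0.62 ± 0.17 and 1.84 ± 0.34 CPM, both higher in every with-peak tumor, with edgeR adjusted p of 0.471 and 0.395.

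**Figure D2:**
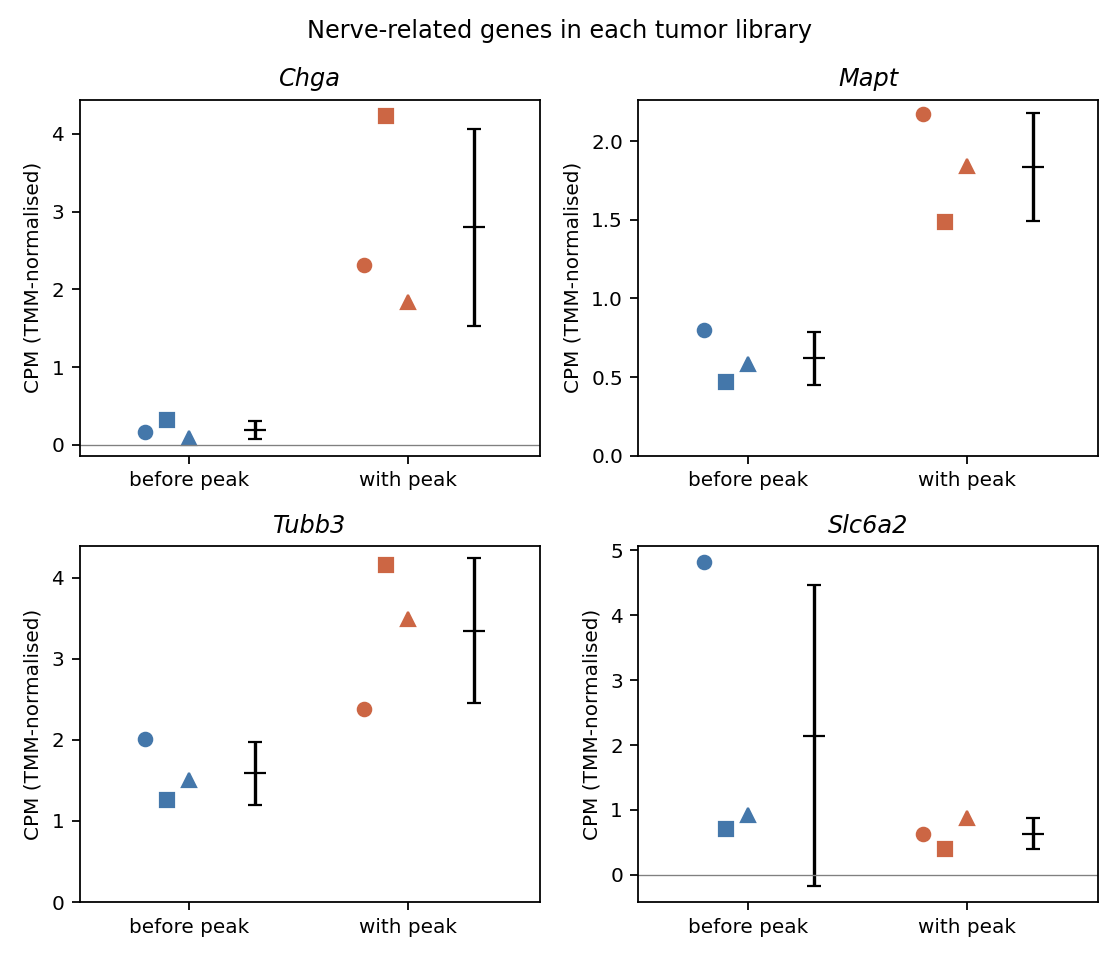
CPM of Chga, Mapt, Tubb3 and Slc6a2 in each tumor (circle, square and triangle are replicates 1, 2 and 3), with the mean and SD of each group of 3 in black. Chga, Mapt and Tubb3 lie higher in every with-peak tumor, while the groups overlap for Slc6a2.

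The synaptic vesicle list had an adjusted p of 0.331, with scores of 2.13 ± 0.04 before the peak and 1.87 ± 0.09 with it (SD, n = 3; exact permutation p = 0.1). Voltage-gated channels had an adjusted p of 0.0758 and a median of 0.11, with 12 of 21 genes positive. This list passes without a filter on low counts (0.00827), with library size alone (0.0311) and without before-peak replicate 3 (4.06e-04) or with-peak replicate 1 (7.16e-04), higher with peak. Its largest log2 fold changes, 2.79 for Cacna1s and 2.22 for Scn4b, come from with-peak replicates 2 and 3, the libraries high in skeletal muscle genes: Cacna1s had 104 and 160 counts there and 8 to 18 elsewhere, and Scn4b 61 and 44 counts there and 5 to 13 elsewhere. Adrenergic receptors (adjusted p = 0.774, Adrb3 and Adra1b at log2 fold changes of -0.92 and -0.62), Schwann cell and glial genes (0.722, Ngfr and Fabp7 at 0.96 and 1.61), neurotrophic factors (0.693, Mdk at 0.89), axon guidance (0.503, Sema3c and Slit2 at 1.48 and -0.71) and glutamate and GABA receptors (0.595, Gabra3 at 1.16) did not pass. The sensory list, with 4 tested genes including Piezo2 and P2rx3, and the cholinergic list, with 2, Chrnb2 and Ache, were too small to test. Median, mean or camera direction differed in sign also for adrenergic receptors, axon guidance, glutamate and GABA receptors, immediate early genes and dendritic cells.

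The interferon response list rose, with 27 of 30 genes positive and a median of 0.55 (adjusted p = 2.30e-09; adjusted p = 0.726 with an estimated correlation). Adjusted over the list alone 0 members passed, and 0 passed over all genes by edgeR; 4 had an unadjusted p under 0.05 and DESeq2 called 0. The score was 4.76, 5.94 and 5.0 in before-peak replicates 1, 2 and 3, against 5.88 to 6.27 with peak, so before-peak replicate 2 lay within the with-peak range. Ifit2 and Isg15, induced by type I interferon, had log2 fold changes of 0.57 and 0.55. Neutrophil genes rose, with 14 of 15 positive and a median of 0.60 (adjusted p = 2.95e-05; adjusted p = 0.726 with an estimated correlation); 1 member, Clec4d, passed adjusted over the list alone and 0 over all genes by edgeR, with 5 at an unadjusted p under 0.05 and 1 by DESeq2. The score was 2.75, 2.45 and 3.59 in before-peak replicates 1, 2 and 3 and 4.09, 3.26 and 3.75 in with-peak replicates 1, 2 and 3, so before-peak replicate 3 lay within the with-peak range. Inflammatory cytokines did not pass (adjusted p = 0.0930, median 0.41), but Il1b, at 95.6 ± 14.0 and 59.9 ± 3.36 CPM, passed adjusted over the list alone with a log2 fold change of -0.68, and Ccl8 had one of 1.30. The cytokine list passes, higher with peak, without before-peak replicate 3 (3.24e-04) or with-peak replicate 3 (4.74e-04), with both left out (1.30e-08) and with library size alone (0.0476).

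Fibroblast genes rose, with 18 of 20 positive and a median of 0.58 (adjusted p = 2.22e-05; adjusted p = 0.726 with an estimated correlation), and so did endothelial genes, with 19 of 20 positive and a median of 0.31 (adjusted p = 0.00975; adjusted p = 0.850 with an estimated correlation). In each of these lists 0 members passed, over the list alone or over all genes by edgeR, with 4 and 2 at an unadjusted p under 0.05 and 0 by DESeq2. Both calls depend on with-peak replicate 2, without which the adjusted p is 0.159 for fibroblast and 0.994 for endothelial genes; the endothelial call is also lost without before-peak replicate 1 (0.15). Carcinoma epithelial genes fell as a list, with 18 of 21 negative and a median of -0.20 (adjusted p = 4.86e-04; adjusted p = 0.726 with an estimated correlation; 0.0515 without before-peak replicate 2). Krt5, a basal keratin, was at 15.2 ± 4.78 and 5.16 ± 1.92 CPM and passed adjusted over the list alone; 0 members passed over all genes by edgeR, with 4 at an unadjusted p under 0.05 and 1 by DESeq2. Proliferation genes fell as a list, with all 26 negative and a median of -0.20 (adjusted p = 5.36e-06; adjusted p = 0.726 with an estimated correlation); 0 members passed in either adjustment, 4 had an unadjusted p under 0.05 and DESeq2 called 0. Mki67 was at 277 ± 43.4 and 211 ± 25.6 CPM. The scores of the groups overlapped for the fibroblast, endothelial, carcinoma epithelial and proliferation lists. Extracellular matrix (adjusted p = 0.0524), pericyte and smooth muscle (0.349), dendritic, mast cell and eosinophil (0.491), adipocyte (0.983), mammary gland (0.468), keratinocyte (0.595), hypoxia (0.628) and immediate early genes (0.750) did not pass. Adjusted over the list alone, 1 mammary gland gene passed, lower with peak. Of the keratinocyte genes, 1 passed in that way higher and 1 lower. Extracellular matrix genes pass, higher with peak, without before-peak replicate 3 (4.34e-04), with-peak replicate 1 (0.00283) or 3 (2.94e-04), and with library size alone (0.0455). Pericyte genes pass, higher with peak, without with-peak replicate 1 (8.04e-04) or 3 (0.016). The largest log2 fold change of that list, 3.79, is that of Des, an intermediate filament gene also of skeletal muscle, at 37.0, 149.9 and 142.9 CPM in with-peak replicates 1, 2 and 3. Adipocyte genes pass in opposite directions, lower with peak without before-peak replicate 2 (0.025) or with-peak replicate 2 (0.0481) and higher with peak without with-peak replicate 1 (0.0318). Mammary gland genes pass, lower with peak, without with-peak replicate 2 (0.00851), and hypoxia genes, lower with peak, without before-peak replicate 1 (0.0126). Among immediate early genes Klf4, at 30.7 ± 2.36 and 52.3 ± 4.30 CPM, passed adjusted over the list alone.

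Skeletal muscle genes rose as a list, with all 24 positive and a median of 2.51 (adjusted p = 1.14e-20; adjusted p = 0.726 with an estimated correlation). Adjusted over the list alone 6 passed, 0 over all genes by edgeR, 12 had an unadjusted p under 0.05 and DESeq2 called 5. The score was highest in with-peak replicates 2 and 3, at 5.34 and 5.29; with-peak replicate 1, at 2.99, lay below before-peak replicate 1, at 3.27, and above before-peak replicates 2 and 3, at 1.75 and 1.18. Ryr1, the calcium release channel of muscle, was at 2.83 ± 1.40 and 22.7 ± 12.4 CPM. Erythroid and platelet genes were highest in the same libraries, with 8 of 8 positive and a median of 2.56 (camera adjusted p = 2.44e-07, or 0.427 with an estimated correlation). Their scores were 6.08 and 6.04 in with-peak replicates 2 and 3, 4.33 in with-peak replicate 1 and 3.41 to 4.09 before the peak. Unlike for muscle, the groups did not overlap in this score (exact permutation p = 0.1). Adjusted over the list alone 4 passed, among them Alas2 and Hbb-bt, and 0 over all genes by edgeR, with 5 at an unadjusted p under 0.05 and 2 by DESeq2. B and plasma cell genes had a score of 5.78 in before-peak replicate 3 against 0.15 to 3.56 in the other libraries, and a median of -1.66 (adjusted p = 0.720). Without that library the B and plasma cell list is higher with peak (9.44e-19), and without before-peak replicate 2 it is lower (0.00329). T and NK cell genes had a median of -0.30 while camera ranked the list upward (adjusted p = 0.491), with a score of 3.59 in the same library and 0.86 to 2.73 in the others. Without that library the T and NK cell list passes, higher with peak (3.68e-08). Gzmb had a log2 fold change of 1.99 and Gzma one of 1.66.

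**Figure D3:**
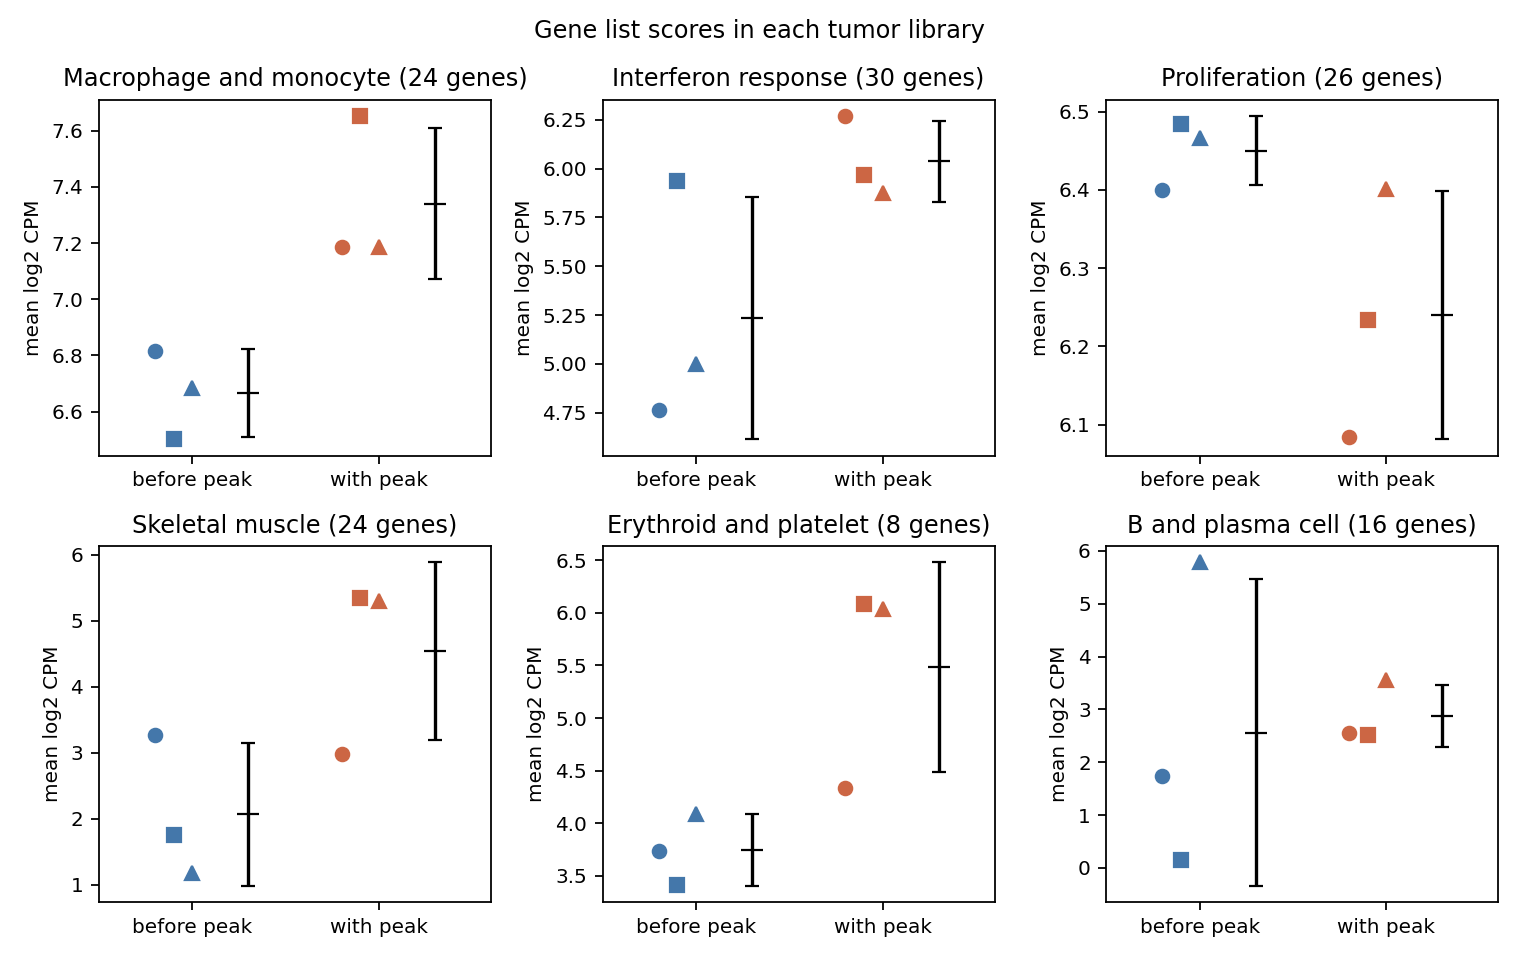
Mean log2 CPM of 6 gene lists in each tumor (circle, square and triangle are replicates 1, 2 and 3), with the mean and SD of each group of 3 in black. Macrophage and erythroid scores do not overlap between groups, muscle and erythroid scores are high in with-peak replicates 2 and 3, and the B cell score is high in before-peak replicate 3.

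Heat shock and unfolded protein genes rose, with 19 of 20 positive and a median of 0.19 (adjusted p = 0.0125; adjusted p = 0.726 with an estimated correlation), but the score was 7.18 in with-peak replicate 3 and 6.34 to 6.42 in the other 5 libraries. The call is lost without before-peak replicate 1 (0.0527) or 3 (0.0625), and without with-peak replicate 3 the direction turns (0.988). Ribosomal protein genes rose, with 28 of 30 positive and a median of 0.18 (adjusted p = 4.97e-05; adjusted p = 0.726 with an estimated correlation), and mitochondrially encoded genes did not pass (0.750). The ribosomal call is lost without both before-peak replicate 3 and with-peak replicate 3 (0.307). The mitochondrial rRNA genes mt-Rnr1 and mt-Rnr2 took 0.0332%, 0.0313% and 0.0456% of counts in before-peak replicates 1, 2 and 3, and 0.0614%, 0.0655% and 0.0587% in with-peak replicates 1, 2 and 3; their log2 fold changes were 0.75 and 0.87 (edgeR adjusted p = 0.117 and 0.142), and DESeq2 called both. In the heat shock and ribosomal lists 0 members passed in either adjustment by edgeR, with 4 and 11 at an unadjusted p under 0.05 and 0 by DESeq2. With library size alone the ribosomal median is 0.13 and the proliferation median -0.26.

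Over all 16755 genes, edgeR called 0 genes higher and 0 lower; the smallest adjusted p was 0.0828. At an unadjusted p under 0.05 there were 1592 genes, 1025 higher and 567 lower, where 837.75 would pass if p-values were uniform and other groupings of the same 6 libraries gave 458 to 1461. With library size alone that split is 768 higher and 1020 lower. DESeq2 called 242 higher and 23 lower, and limma-voom called 0 and 0. The groups did not overlap for 15.5% of genes, where chance gives 10%. The libraries' first principal component carried 32.0% of the variance and the second 24.3%, on which before-peak replicate 3 lay apart at -61.9.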

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

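The newer quasi-likelihood method, the fit without robust estimation and the fit of 2 against 2 tumors, without before-peak replicate 3 and with-peak replicate 3, were chosen after seeing the data. For genes, 0 were called higher and 0 lower with RLE size factors, library size alone, upper quartile scaling, at least 1 CPM in 3 libraries, an absolute log2 fold change of at least 1, limma-voom with or without weights, the newer method and no robust estimation. DESeq2 called 242 higher and 23 lower, no filter on low counts 26 and 3, an adjusted p under 0.1 32 and 3, and 2 against 2 called 4 and 0; the cause was not tested. The labels state no pairing by replicate number. Deviations of same-numbered tumors from their group means correlated at -0.06, -0.10 and 0.03, which shows no pairing but cannot exclude a weak one. With the replicate number as a block 1 gene was higher and 0 lower, and voltage-gated channels passed (0.0461). Leaving out 1 library gave 0 to 17 genes higher and 0 lower, the 17 without before-peak replicate 2, 13 without before-peak replicate 3 and 9 without with-peak replicate 1. On simulated counts of 3 against 3 tumors, 13.1% of edgeR calls were false. Fits without 1 library were not simulated, so how many of these few calls are false is uncertain. The calls without with-peak replicate 1 include Des, Ryr1, Alas2, Hal and Cd5l. Without before-peak replicate 2, the interferon list had a camera adjusted p of 2.28e-43. Lists called higher were 7 to 13 and lower 2 to 4 over these omissions, and 14 and 2 with 2 against 2, where ribosomal genes were lost (0.307) and cytokine, matrix, T and NK cell, pericyte, voltage-gated channel and dendritic genes gained, higher with peak (1.30e-08, 4.16e-07, 1.56e-08, 0.00769, 0.00349 and 0.0210). With an estimated correlation or fry, lists called were 0 higher and 0 lower, and the macrophage list had an adjusted p of 0.427 and 0.28, against 7.19e-25 to 1.39e-14 on leaving out 1 library. By camera or the directional fry test, sympathetic genes did not pass in any of these settings (0.427 to 0.994). The mixed test of fry gave them an adjusted p of 0.0419. Direction reversed for adipocyte genes (0.0250 without before-peak replicate 2, 0.0481 without with-peak replicate 2, up to 0.988; 0.0318 in the main direction without with-peak replicate 1), B and plasma cell genes (9.44e-19 without before-peak replicate 3, 1.11e-13 in 2 against 2, up to 0.994) and heat shock genes (0.988 without with-peak replicate 3, from 7.57e-05 over the other omissions; 0.993, not reversed, in 2 against 2). Depth limits genes near 1 CPM, such as Chga and Mapt.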

Other observations

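Beyond the lists, several single genes had DESeq2 calls or small edgeR p-values, all chosen after their values were seen. Cd5l, a protein secreted by tissue macrophages, was at 1.38 ± 0.63 CPM before the peak and 22.7 ± 11.6 CPM with it (log2 fold change 4.03, SE 0.54, edgeR adjusted p = 0.0976). Psap and Ctss, a lysosomal activator protein and a cathepsin, had log2 fold changes of 0.66 and 0.87 (edgeR adjusted p = 0.0997 and 0.0976). Mcpt2 and Mcpt1, mucosal mast cell proteases, had lower values with peak, at 9.75 ± 2.55 and 2.23 ± 0.76 CPM for Mcpt2 (log2 fold change -2.11, edgeR adjusted p = 0.0976) and a log2 fold change of -2.65 for Mcpt1 (edgeR adjusted p = 0.270). The fixed list that holds other mast cell genes did not pass.

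Immunoglobulin genes were abundant in 4 libraries. Their summed CPM, on total counts, were 50.7 and 38.6 in before-peak replicates 1 and 2, 964 in before-peak replicate 3, and 378, 637 and 450 in with-peak replicates 1, 2 and 3. Cxcl9, a chemokine induced by interferon-gamma and picked after its values were seen, was at 2.25 and 12.3 CPM in before-peak replicates 1 and 3, at 59.6 CPM in before-peak replicate 2 and at 70.4 to 199 CPM with peak.

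The tests below were chosen after the results were seen, except those on further muscle and lymphoid genes, some of which were already in the results. The lysosomal genes may be higher as a set. Of 45 textbook lysosomal genes, without the 6 already noticed, 40 were positive and 17 passed adjusted over the set alone. Camera gave an unadjusted p of 8.19e-13 with the preset correlation and 0.0434 with an estimated one. Before adjustment over lists, camera with an estimated correlation gave a p of 0.0210 for macrophage and 0.0267 for erythroid genes. The value of 0.0434 thus does not set the lysosomal genes apart from these lists. None of the 45 is in the macrophage list, but macrophages are rich in lysosomes, so a separate lysosomal change and a larger macrophage share remain open.

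The muscle transcripts may come from skeletal muscle in the dissected pieces. Of 10 tested muscle genes outside the list, 9 had with-peak replicates 2 and 3 as their highest libraries. Among them, Pgam2 was at 22.3 and 15.6 CPM there against 1.75 to 4.41 CPM elsewhere. Pgam2, Cox6a2, Xirp2 and Jsrp1 were already among the DESeq2 calls. Genes of the muscle list moved together (estimated correlation 0.85), so other muscle genes in the same libraries repeat the pattern and cannot show its source. A rise shared by all with-peak tumors stays open. Over the 24 muscle genes, with-peak replicate 1 had a median log2 ratio of -0.31 to before-peak replicate 1 but of at least 1.28 to before-peak replicates 2 and 3. Of the 24, 9 were higher in every with-peak tumor than in every before-peak tumor. Whether larger or older tumors reached into muscle also stays open, since the labels give neither size nor age.

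The lymphoid transcripts of before-peak replicate 3 may come from lymph node tissue in the dissected piece. Of 9 tested lymph node and naive lymphocyte genes, 8 were highest in that library. Ccr7, among the 8, is also in the fixed dendritic, mast cell and eosinophil list, so it was not new to the results. B and plasma cell genes moved together (estimated correlation 0.93), so this check repeats the pattern and cannot show its source. Stromal genes that would mark a node, such as Madcam1 and Chst4, were not tested here, so lymphoid aggregates within the tumor remain open. No biological explanation was tested for the muscle and lymphoid transcripts.

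For the macrophage list, the lymphoid library is argued against as the cause, since the score difference was 0.68 without it and 0.67 with it. A lower share of carcinoma cells could raise every other cell type alike. The macrophage score minus the mean of the endothelial, pericyte, adipocyte, dendritic and T and NK lists was 0.46 higher with peak. Its standard error was 0.33, so the value is between 1 and 2 standard errors and decides nothing. These 5 lists leave out fibroblast and neutrophil genes, which rose with medians of 0.58 and 0.60. The T and NK score of 3.59 in before-peak replicate 3 enlarges the difference, and the difference without that library was not tested. Tumor age and the peak itself remain open, as the design joins them, and so does RNA quality or selection, since the mitochondrial rRNA share also separates the groups. The ribosomal protein score, at 9.82 to 9.94 before the peak and 9.98 to 10.16 with it, separates them too, as does the erythroid score. Of the 10 splits of the 6 libraries, 1 moved the macrophage list as much, the real one, at a mean log2 fold change of 0.67 against 0.45 in size for the highest other. The unadjusted camera p of this list, with the preset correlation, was 1.27e-22 in the real split and 1.09e-11 to 0.761 in the others. Very small camera p-values thus also arose under wrong groupings, though each of these still keeps 2 tumors of 1 group together. The same 10 splits gave 1592 genes at an unadjusted p under 0.05 by edgeR for the real one, matched by 1 split, the real one itself, against 1461 for the highest other. They gave 265 genes by DESeq2 for the real one, again matched by 1 split, against 152 for the highest other, 0 genes by edgeR in all 10 splits, with 0 for the highest other, and 11 called lists, reached by 7 splits, against 17 for the highest other; 10 splits are too few for a share under 0.05.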
